A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

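Total RNA from leaf sheaths of field-grown rice (Oryza sativa, cultivar Nipponbare) was labelled with Cy3 and hybridised to 1-colour Agilent rice oligonucleotide arrays, per the labels. There were 6 arrays, 3 from wild-type plants (WT) and 3 from the smos1 mutant. The labels state that the 3 samples of each genotype were biological replicates, and they do not say how many plants went into each sample, at what age or hour the sheaths were taken, or what kind of mutation the line carries. Each array held 45151 spots, of which 2007 were control spots, and 42418 distinct probes remained. Of these probes, 41908 carried a rice locus identifier in their name, for 29690 loci.

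The arrays were read with Agilent Feature Extraction 9.5.3.1, per the file headers, which also give the background-subtracted and spatially detrended spot intensity that was used here. That deposited intensity is linear, is not scaled between arrays, and takes a small substitute value where a spot did not stand above its background. A table of the authors' processed log2 values for the same arrays was deposited as well, with its scale, centring and offset unstated. Each of its columns equalled the scanner intensity of that array times a constant, with a small negative offset, on a log2 scale (Pearson r across spots of 0.99946 or higher), so that the scale is known and the reason for the constants and offsets is not. The column medians were 9.25, 9.17 and 9.16 for WT replicates 1, 2 and 3, and 9.05, 8.96 and 8.83 for smos1 replicates 1, 2 and 3. That table served as an alternative.

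The main values were log2 intensities minus the 75th percentile of each array over non-control spots. Repeated spots of a probe were averaged, and spots marked as non-uniform or population outliers (3 to 15 per array) were left out. A probe entered the test when it was well above background on all arrays of at least 1 genotype, which left 36024 probes for 24890 genes. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, smos1 minus WT, no covariate), with Benjamini-Hochberg adjustment over probes, and a change was called at an adjusted p under 0.05. A gene was represented by its tested probe with the highest mean over all arrays. No gene had called probes in both directions, and 2 called genes had another tested probe with the opposite sign. For 20 called genes the probe came from a transcript that the array design also used for another locus. Errors of log2 fold changes are limma's standard errors, and levels are means with the SD over 3 arrays.

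Where a probe was not well above background on any array of 1 genotype, the fold is given as a bound. The mean of the bright genotype was set against the mean, over the arrays of the dim genotype, of the higher of the probe's own value and the lowest value among probes well above background on that array. Where the probe's own values were the higher ones, the bound equals the fitted fold. Bounds hold for the background subtraction of the main values alone. A gene's identity is the locus and description in the scanner files, which follow an old annotation. A reference table of gene symbols for assembly ASM3414082v1 was at hand, but it does not list the locus identifiers used on the array, so no coordinates are printed, and the chromosome is the one encoded in the locus identifier. The symbols SMOS1, DLT and those of clock and hormone genes were assigned by locus before the data were examined.

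Before the data were examined, 39 gene lists were fixed for cell walls, the cytoskeleton, hormones, stress, growth and other tissues, by words in the gene description or by locus. Lists were tested with camera at a preset correlation of 0.01 between genes, for the 35 lists with at least 3 tested genes, with the correlation estimated per list and the self-contained test fry beside it. Of the 11 lists called, 0 were called with an estimated correlation and 4 by fry, namely the xyloglucan, EXORDIUM, tubulin and kinesin lists. With an estimated correlation camera also rests on the residual degrees of freedom, 4 over all arrays, so few lists could pass. For the xyloglucan list this correlation was -0.023, below the preset, yet the camera p went from 0.00622 to 0.0467. A call lost with an estimated correlation therefore does not by itself show that correlation between genes removed it. Setting genes above background in only 1 genotype at their bound moved no list median (largest shift 0). No list held more than 1 such gene, so a median could hardly have moved. The lists of diterpenoid phytoalexin enzymes and of NAC factors matched no locus, and those of cytokinin genes and root markers had 2 tested genes each. The locus fixed for GID2 was left out because the files describe it as another protein. The list of pathogenesis-related proteins also took in 36 tested genes whose description contains the word methionine and 31 ERF-domain factors, SMOS1 among them, and a cleaned version was among 6 lists added after the descriptions had been read. The pattern for that version was corrected once more after its first values had been seen, since it still took in methionine enzymes.

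The rule for named genes was also set before the data were examined. It takes SMOS1, DLT and the called members of the EXORDIUM and PHI-1 family. It further takes the 10 largest rises and 10 largest falls among called genes with a description, above background on all arrays and with non-overlapping groups. Per direction it adds the 3 described genes with the largest bound, and from each list the 3 members with the smallest p. The rule gave 135 genes, of which 79 were called. An item among the 10 largest falls is not reported here.

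The precision is limited by the number of arrays, with 4 residual degrees of freedom. In data simulated from these arrays' own means and spreads, with 36008 probes and 200 of them changed, the fit called 23.9% of probes changed 4-fold, 64.2% of those changed 16-fold and 80.3% of those changed 64-fold. It also called 5 unchanged probes there, and 0 probes when none was changed, by the same limma fit. A planted list of lowered genes was called and none of the 38 unchanged lists was. The simulated probes were drawn independently of each other. They therefore do not show how often camera at its preset correlation calls lists whose genes are correlated.

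The arrays lay on 3 slides, each with its own scan time on 1 day. Slide 1 held WT replicates 1 and 2 with smos1 replicates 1 and 2, slide 2 held WT replicate 3, and slide 3 held smos1 replicate 3. Alternatives set before the data were examined were normexp background correction with an offset of 50, quantile normalization, median centring, other filters on dim probes, the authors' log2 table, a variance trend with a robust prior, the slide as a fixed or random block, slide 1 alone, the replicate number as a block, each array left out in turn, the mean over a gene's probes, and a 2-fold minimum. After the data had been seen, a fit without WT replicate 2 and smos1 replicate 3, a corrected normexp fit and the list test with an estimated correlation under each alternative but the random block were added. In the corrected normexp fit, local backgrounds over 10 times the array median were set to that median. Only smos1 replicate 3 had such spots, 10 of them. Its median log2 signal before scaling was 10.31 in the planned normexp fit and 9.35 in the corrected one. Values given below under planned normexp correction carry this shift of 1 array.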

Results

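Gene expression in the leaf sheath, the part of the rice leaf that wraps the stem, was compared between WT Nipponbare and the smos1 mutant, with 3 arrays per genotype. SMOS1 encodes a transcription factor of the AP2/ERF type that acts in the growth of rice organs downstream of auxin and brassinosteroid, and the comparison asks which transcripts differ when it is mutated. Between 84.6% and 88.6% of the 42418 probes were well above background on each array, and the 75th percentile of the spot signal lay between 2762 and 3979 intensity units. No spot was saturated. Pairwise correlations across probes were 0.921 to 0.952 within WT and 0.905 to 0.975 within smos1. WT replicate 2 had correlations of 0.952 and 0.921 with the other WT arrays and of 0.94, 0.921 and 0.916 with the smos1 arrays, across probes, which are not independent of each other. On the first principal component, which held 55.5% of the variance, it scored -27.4, against -155.3 and -159.1 for the other WT arrays and 66.6 to 137.9 for the smos1 arrays.

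The mutated gene was checked first. SMOS1 (Os05g0389000, chromosome 5) had log2 signals of 0.46 ± 0.38 relative to the array's 75th percentile in WT and -4.09 ± 1.10 in smos1 (mean ± SD, n = 3 arrays each). This was a log2 fold change of -4.55 ± 0.57 (SE), or 23.5-fold lower, with a limma adjusted p of 0.0206. The groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 can give. The probe stayed above background on all 3 smos1 arrays, and the labels do not place the mutation, so the signal shows the level of the probed part of the transcript alone. Within slide 1 the log2 fold change was -5.08, with a limma adjusted p of 0.0319. Without smos1 replicate 3 it was 36.5-fold lower. The call was lost without WT replicate 1 (adjusted p = 0.0873), WT replicate 3 (0.0668), smos1 replicate 1 (0.0869) or smos1 replicate 2 (0.0612).

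DLT (Os06g0127800), a GRAS-domain factor of brassinosteroid signalling that is known to act with SMOS1, fell by 3.85 ± 0.69 on the log2 scale (14.4-fold, adjusted p = 0.0362). The EXORDIUM and PHI-1 family encodes secreted proteins linked to growth in response to brassinosteroid and phosphate, and 4 of its 10 tested members fell while none rose. The Phi-1 protein gene Os02g0757100 was 8.23-fold lower in smos1 (log2 fold change -3.04 ± 0.30), Os06g0133600 was 8.70-fold lower and another Phi-1 protein gene, Os02g0756200, was 5.02-fold lower. Os07g0496700 was above background only in WT and at least 17.2-fold lower in smos1, but its log2 fold change was -0.38 under planned normexp correction. There were 5 members lower and 1 higher when adjusted over the list alone. The list as a whole was called lower by camera (median log2 fold change -1.72, adjusted p = 0.00924), with adjusted p = 0.59 with an estimated correlation. Within slide 1 its median was -2.40. The call of the list was lost without WT replicate 2 (adjusted p = 0.0772) and without both WT replicate 2 and smos1 replicate 3 (0.124). Within slide 1 none of the 4 genes or DLT passed the test (adjusted p from 0.0538 to 0.0719), nor did any of them without WT replicate 1 or 3 or smos1 replicate 1 or 2.

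**Figure D1:**
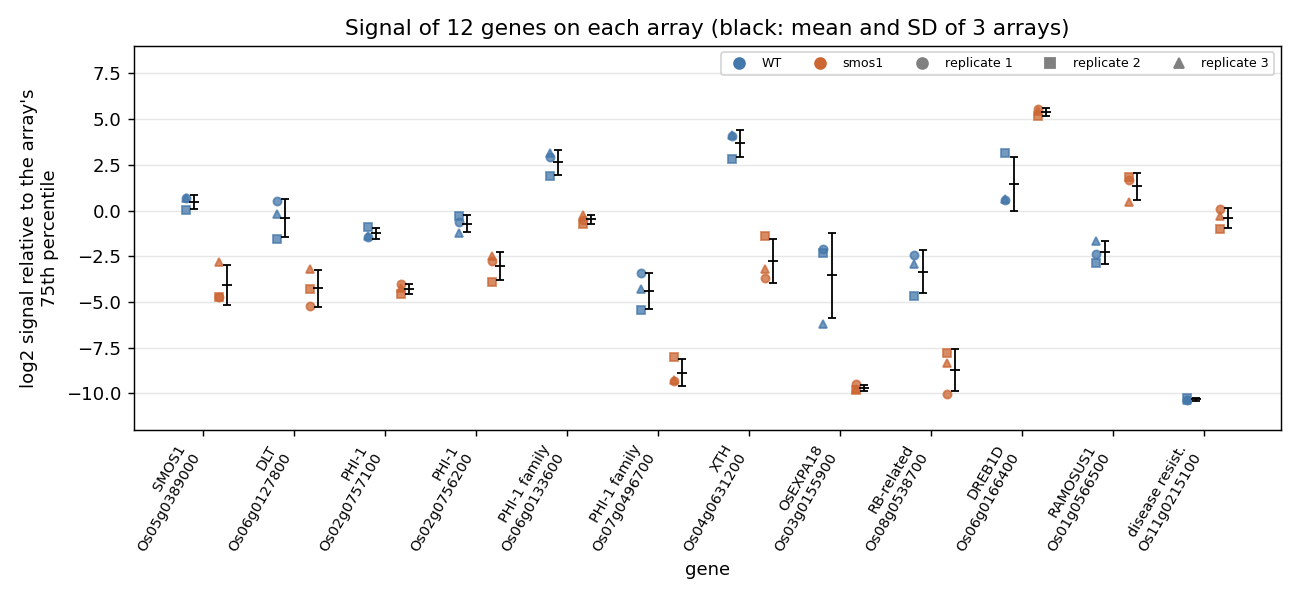
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 genes (horizontal axis) on each of the 6 arrays, WT in blue and smos1 in orange, with the replicate as the marker and black bars for the mean ± SD of 3 arrays. SMOS1 averaged 0.46 in WT and -4.09 in smos1, DLT and the 4 EXORDIUM and PHI-1 genes were lower in all smos1 arrays than in any WT array, and Os11g0215100 averaged -10.33 in WT and -0.41 in smos1.

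Over the 24890 genes tested, 1259 were called, of which 944 (75%) were lower and 315 higher in smos1. Each called gene differed by more than 2-fold, with a median absolute log2 fold change of 3.01. At an unadjusted p under 0.05 there were 6793 genes, and the groups did not overlap for 33.4% of genes against 10% expected by chance. Of the called genes, 61 were not above background on any WT array and 62 were not above background on any smos1 array. Relative to the 75th percentile the median log2 fold change over all genes was 0.07. It was 0.18 after median centring, 0.36 under planned normexp correction and 0.10 in the corrected normexp fit. The number of calls depended strongly on single arrays. It was 12 without WT replicate 1, 30 without WT replicate 3, 13 without smos1 replicate 1 and 46 without smos1 replicate 2. It rose to 3356 without WT replicate 2, to 1748 without smos1 replicate 3, and to 4953 without both, a removal chosen after seeing the data. Within slide 1, which held 2 arrays of each genotype, 186 genes were called, 89 higher and 97 lower. Of the 134 named genes other than SMOS1, 56 were not called in the main fit and had no call to lose. Among the called ones, the call was lost for 75 without WT replicate 1 and 73 without WT replicate 3. It was lost for 74 without smos1 replicate 1, 71 without smos1 replicate 2 and 65 within slide 1. Each time these were most of the named genes that had been called. Of the 79 named genes that were called, 29 had a fold that leaving out 1 array moved by over 1.5 times, and 49 had a fold smaller by over 1.5 times under planned normexp correction. All 1259 genes kept their direction within slide 1, and 118 of them were called there. The slide as a fixed block also gave 186 calls, and planned normexp background correction gave 6, all higher and none lower. With 10 extreme local backgrounds on smos1 replicate 3 set to the array median, normexp gave 908 calls, 216 higher and 692 lower. Of the named genes other than SMOS1, 17 lost their call there and 0 turned their sign, against 75 and 1 in the planned fit.

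Among called genes with a functional description, above background on all arrays and with non-overlapping groups, the largest fall was in an osmotin-like protein (Os01g0839900). It fell by 7.07 ± 1.09 on the log2 scale (134-fold). A thionin (Os02g0629800) was 55.2-fold lower, and 3 neighbouring glutathione S-transferase genes on chromosome 3 (Os03g0134900, Os03g0135100 and Os03g0135200) were 99.7-, 66.8- and 91.2-fold lower. A xyloglucan endotransglycosylase (Os04g0631200) was 86.5-fold lower, and a family 16 glycoside hydrolase (Os10g0117000) was 58.7-fold lower. A plastocyanin-like protein (Os09g0557900) had the smallest adjusted p of these falls (64.5-fold lower, 0.00682). An ERF-type factor described as similar to AtERF5 (Os01g0657400) was 62.5-fold lower. Genes above background only in WT included the expansin OsEXPA18 (Os03g0155900), at least 37.1-fold lower in smos1. Others were a pollen allergen and extensin domain protein (Os09g0508200), at least 37.7-fold lower, and a retinoblastoma-related protein (Os08g0538700), of a family that controls entry into DNA synthesis, at least 31.5-fold lower. Under planned normexp correction the log2 fold changes of these 3 genes were only -1.20, -1.36 and -1.29 in that order, and none was called. Apart from the plastocyanin-like protein, single arrays moved the folds of these falls by over 1.5 times. The osmotin-like protein was 57.9-fold lower without smos1 replicate 1 and 231-fold lower without smos1 replicate 2. The glutathione S-transferase genes were 250-, 182- and 231-fold lower without WT replicate 2, and their lowest folds, each without another array, were 49.2, 40.3 and 55.6. Without smos1 replicate 2 the xyloglucan endotransglycosylase, the glycoside hydrolase and the AtERF5-like factor were 138-, 120- and 121-fold lower. The thionin was 31.5-fold lower without smos1 replicate 3. Without WT replicate 1 none of the falls named here in genes above background on all arrays was called. Apart from the plastocyanin-like protein, none of them was called without WT replicate 3 or without smos1 replicate 1 either. Some also lost their call without smos1 replicate 2 or 3.

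The largest rises of genes with a functional description, above background on all arrays, were in a glycine-rich protein (Os07g0511100, 34.3-fold) and in a gene described as an eggshell protein family member (Os12g0242100, 32.2-fold). A dioxygenase of the isopenicillin N synthase family (Os01g0832600, 28.6-fold) and a nitrate transporter (Os12g0638300, 23.6-fold) followed. Regulators that rose were an ERF-domain factor (Os05g0572000, 22.1-fold), a LOB domain protein (Os03g0287400, 19.7-fold), a gene described as a transcription factor (Os01g0274800, 18.7-fold), DREB1D (Os06g0166400, 15.2-fold) and a RING finger protein (Os03g0142500, 14.2-fold). DREB1D belongs to a family of cold and dehydration response factors. The gene described as dioxygenase RAMOSUS1 (Os01g0566500), a family that makes strigolactone, a hormone that limits branching, was 12.2-fold higher. The adjusted p of these 10 genes lay between 0.0162 and 0.0410. Without WT replicate 1 or 3 or smos1 replicate 1 none of them was called. Without smos1 replicate 2 only the LOB domain protein among them was called, and some lost their call without smos1 replicate 3. Single arrays moved 7 of these folds by over 1.5 times, most often WT replicate 2, without which Os12g0242100 was 61.6-fold and Os01g0832600 59.9-fold higher. Without WT replicate 3 they were 19.5- and 17.9-fold higher. The nitrate transporter ranged from 14-fold without WT replicate 1 to 36.4-fold without smos1 replicate 1.

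Genes above background only in smos1 had larger bounds, and the 3 described genes with the largest bounds lay in 1 stretch of 37 tested loci on chromosome 11. Os11g0215100, a disease resistance response protein, averaged -10.33 in WT and -0.41 in smos1, which is at least 415-fold higher (adjusted p = 0.000388). The NBS-LRR-like gene Os11g0224900 was at least 208-fold higher and Os11g0226800, another NBS-LRR homologue, was at least 119-fold higher. For Os11g0226800 the bound equals the fitted fold, since its own WT values entered the bound. NBS-LRR proteins are intracellular receptors of plant immunity. A further 4 loci of the same stretch, chosen after their values were seen, were also above background only in smos1. These were Os11g0214400 (at least 105-fold), Os11g0225300 (at least 105-fold), Os11g0226400 (at least 74.7-fold) and Os11g0226700 (at least 76.5-fold). The 3 genes that the rule named were called without each array in turn and within slide 1, with a highest adjusted p of 0.0203. Under planned normexp correction their log2 fold changes were 5.54, 4.48 and 4.03, smaller than the bounds above, and Os11g0224900 lost its call (adjusted p = 0.0502). The bounds are therefore not lower limits under every background correction.

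**Figure D2:**
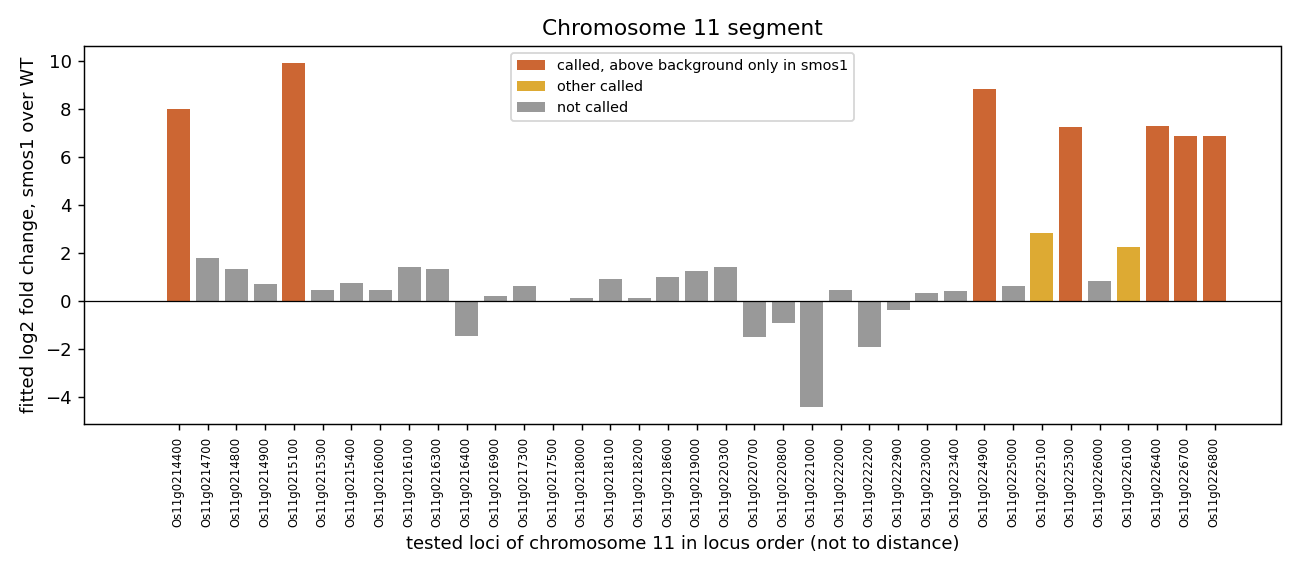
Fitted log2 fold change of smos1 over WT (vertical axis) for the 37 tested loci from Os11g0214400 to Os11g0226800 in locus order (horizontal axis), from 3 arrays per genotype. The 7 loci above background only in smos1 (orange) had fitted values from 6.88 to 9.92 that, apart from that of Os11g0226800, are not bounds, 2 further loci were called (yellow), and 28 were not called (grey).

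Among lists of cell wall proteins, 4 were called lower in smos1 by camera at its preset correlation and none with an estimated correlation. Of 33 expansins, proteins that loosen the wall during cell expansion, 6 fell and 1 rose. A beta-expansin (Os04g0530100) was 26.1-fold lower and an expansin (Os06g0718100), above background on 2 of 3 smos1 arrays, was 9.72-fold lower, while expansin-like protein A (Os03g0132200) was 9.88-fold higher. Under planned normexp correction the log2 fold change of Os06g0718100 was -0.75 (adjusted p = 0.581), and without WT replicate 2 the beta-expansin was 41.9-fold lower. Of 47 pectin-modifying enzymes 6 fell and none rose, among them a pectinesterase (Os02g0783000, 31.1-fold), a polygalacturonase subunit (Os08g0380100, 9.96-fold) and a polygalacturonase-like protein (Os12g0554800, 9.09-fold). Of 20 fasciclin and arabinogalactan proteins 4 fell and none rose, including Os08g0502400 (14.1-fold), Os01g0668100 (7.51-fold) and Os04g0574200 (7.29-fold). Of 9 xyloglucan endotransglucosylases only Os04g0631200 was called. Os06g0696500 and Os04g0604300 had log2 fold changes of -3.11 and -2.12 with adjusted p of 0.0609 and 0.0512. Adjusted over the list alone, the genes lower and higher were 12 and 1 for expansins, 13 and 2 for pectin enzymes, 11 and 0 for fasciclin proteins and 3 and 0 for xyloglucan enzymes. The camera adjusted p was 0.000456, 0.0161, 2.97e-07 and 0.02 in that order. With an estimated correlation the adjusted p was 0.59, 0.611, 0.59 and 0.59. Their median log2 fold changes were -1.31, -0.46, -1.25 and -1.02, and within slide 1, which lacks smos1 replicate 3, they were -1.41, -0.61, -2.06 and -1.14. The arrays of each genotype did not lie together in these lists. Relative to the WT mean, smos1 replicate 3 had medians of -0.44, -0.15, -0.91 and -0.22, against -1.46, -0.83, -1.29 and -1.19 in smos1 replicate 1 and -1.45, -0.73, -2.21 and -1.23 in smos1 replicate 2. WT replicate 2 was at -0.27, -0.21, 0.05 and -0.19, so that for pectin enzymes it lay below smos1 replicate 3. With no filter on dim probes the xyloglucan and pectin lists lost their calls (adjusted p of 0.0851 and 0.926), with medians of -0.36 and 0.37. Under planned normexp correction the xyloglucan list kept its call towards lower with a median of 0.05.

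Lists of histones, cell cycle genes, cytoskeletal proteins and ribosomal proteins were also called lower by camera at its preset correlation, and none of them with an estimated correlation. Of 46 histones, 14 fell and none rose, for example histone H4 (Os04g0583600, 19.3-fold), histone H2A (Os03g0279200, 13.8-fold) and histone H3.2 (Os05g0489800, 9.63-fold). Of 10 cell cycle genes 3 fell, namely a B-type cyclin (Os06g0726800, 30.2-fold), the spindle checkpoint protein MAD2 (Os04g0486500, 23.5-fold) and PCNA (Os02g0805200, 7.88-fold), the sliding clamp of DNA replication. Without WT replicate 2, histone H4 and PCNA were 30.3- and 12.5-fold lower. Of 55 kinesins and microtubule-associated proteins, motors and organisers of the spindle and cortical microtubules, 14 fell and none rose, with Os12g0590500, above background on 1 of 3 smos1 arrays, at 31.1-fold and Os05g0459400 and Os03g0587200 at 19.4- and 19.2-fold. The log2 fold change of Os12g0590500 was -1.41 under planned normexp correction (adjusted p = 0.374). Of 14 tubulins, 2 fell, both beta-tubulins (Os01g0805900, 4.71-fold, and Os05g0413200, 4.23-fold). A further beta-tubulin, Os03g0105600, had a log2 fold change of -2.94 and an adjusted p of 0.0542. Of 147 cytosolic ribosomal proteins 1 was called, S10-1 (Os01g0962600, 6.31-fold lower), but 143 had a log2 fold change below 0, with a median of -1.08. The ribosomal proteins L30 (Os01g0276000) and L10a (Os02g0321900) had log2 fold changes of -1.45 and -1.90 with adjusted p of 0.0530 and 0.0569. Adjusted over the list alone, 24 histones, 3 cell cycle genes, 24 kinesins and related proteins, 9 tubulins and 96 ribosomal proteins were lower, and 1 tubulin and 1 ribosomal protein were higher.

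The camera adjusted p of these 5 lists was 2.12e-11 for histones, 0.00512 for the cell cycle, 2.45e-08 for kinesins, 6.34e-05 for tubulins and 1.49e-21 for ribosomal proteins. With an estimated correlation the adjusted p was 0.59 for kinesins and tubulins and 0.611 for the other 3 lists. The estimated correlation between genes was 0.674 for histones and 0.835 for ribosomal proteins. Within slide 1 the median log2 fold changes were -1.35 for histones, -1.22 for the cell cycle, -1.39 for kinesins, -1.20 for tubulins and -0.88 for ribosomal proteins. WT replicate 2 lay below the other WT arrays in these lists, to an extent that differed by list. Relative to the WT mean, its median was -1.10 for histones against 0.53 and 0.59 in the other WT arrays, and -0.61 for ribosomal proteins against 0.33 and 0.29. The smos1 medians were -1.36 to -1.68 for histones and -0.96 to -1.23 for ribosomal proteins. For the cell cycle WT replicate 2 was at -0.85, against 0.32 and 0.26 in WT and -0.91 to -1.55 in smos1. For kinesins it was at -0.41, against 0.36 and 0.16 in WT and -0.68 to -1.42 in smos1. For tubulins it was at -0.19, near the other WT arrays (0.17 and 0.11) and apart from smos1 (-1.08 to -1.36).

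**Figure D3:**
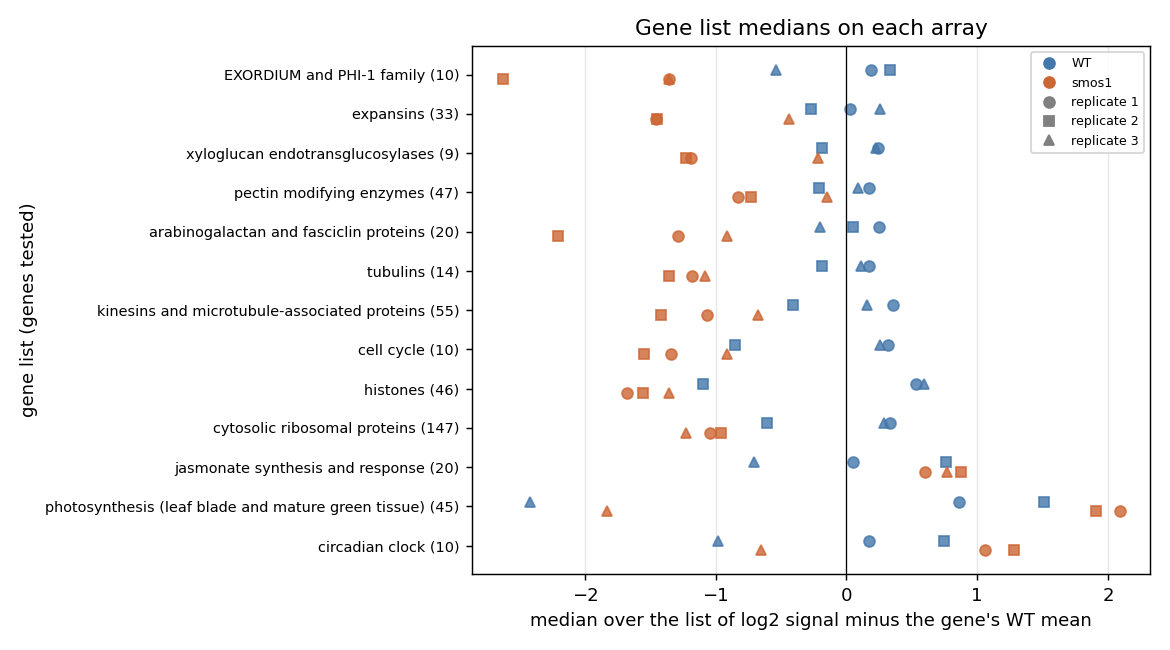
Median over each gene list of the log2 signal minus the gene's WT mean (horizontal axis), for the 11 called lists and 2 lists that stand for green tissue and time of sampling (vertical axis), with WT in blue, smos1 in orange and the replicate as the marker. Histone medians ran from -1.36 to -1.68 on the smos1 arrays, with WT replicate 2 at -1.10, and photosynthesis medians were -2.42 and -1.83 in replicate 3 of WT and smos1 and 0.86 to 2.09 on the other arrays.

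The list of jasmonate synthesis and response genes was the only list called higher by camera (median log2 fold change 0.93, adjusted p = 0.02), with adjusted p = 0.611 with an estimated correlation. Of its 20 tested members 1 rose, the lipoxygenase Os12g0560100 (3.13-fold), whose probe came from a transcript also used for another locus. The 1 that fell was Os02g0753300 (3.11-fold), described as containing a lipoxygenase LH2 domain. Another lipoxygenase, Os12g0560200, had a log2 fold change of 2.47 and an adjusted p of 0.0596. Lipoxygenases start the pathway to jasmonate, a defence hormone. With p adjusted over the list alone, 3 members were higher and 1 was lower. Within slide 1 the median was 0.31 and the list was not called (adjusted p = 0.24), nor was it with the slide as a fixed block (0.239), without WT replicate 3 (median 0.52, 0.274) or under planned normexp correction (0.0616). WT replicate 2, at 0.76, lay within the range of the smos1 arrays (0.60 to 0.88) in this list, whereas the other WT arrays were at 0.05 and -0.71.

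Hormone lists other than jasmonate were not called by camera under the main settings, and none was called with an estimated correlation under any alternative but the slide as a random block, where it was not run (lowest adjusted p = 0.426 over all lists). Among 14 brassinosteroid genes only DLT was called, and the kinase GSK2 (Os05g0207500) and the synthesis gene BRD2 (Os10g0397400) had log2 fold changes of -1.63 and -1.74 with adjusted p of 0.0543 and 0.141. The median of the list was -0.62 (camera adjusted p = 0.0683), and the list was called lower in 7 of 20 alternatives, among them slide 1 alone (median -0.87, 0.00866) and the fit without smos1 replicate 3 (-0.87, 0.012). Among 14 auxin response factors, which mediate transcription under auxin, 1 rose (Os06g0702600, 4.85-fold) and 1 fell (Os04g0664400, 42.8-fold, above background on 2 of 3 smos1 arrays). The latter was 21.4-fold lower without smos1 replicate 1, and its log2 fold change was -1.84 under planned normexp correction (adjusted p = 0.275). Their median was 0.24 and their mean -0.09, and the camera test leaned higher (adjusted p = 0.641). Of 24 Aux/IAA genes, repressors of auxin response, 1 fell (Os03g0797800, 10.4-fold, from 8.36 without WT replicate 3 to 16 without WT replicate 2). Their median was 0.02 and their mean -0.09, with a camera adjusted p of 0.97 towards higher. Of 19 SAUR genes 1 fell (Os08g0452500, log2 fold change -1.63 ± 0.29), with a list median of -0.69 (0.351). None of 12 GH3 genes, which conjugate auxin, was called, and 9 had values above 0 (median 1.12, camera adjusted p = 0.0667). That list was called higher in 3 alternatives, without smos1 replicate 1 (0.0384), without smos1 replicate 2 (0.0426) and in the authors' deposited log2 table (0.0477). Of 15 gibberellin genes the deactivating enzyme EUI (Os05g0482400) was 2.78-fold higher and none fell (median 0.52, camera adjusted p = 0.173). None of 12 ethylene, 29 abscisic acid and dehydration and 2 cytokinin genes was called (medians 0.06, 0.49 and -0.09), with camera adjusted p of 0.29 and 0.162 for the first 2 lists, and the abscisic acid list was called higher without smos1 replicate 2 (0.0458). Adjusted over the list alone, the genes higher and lower were 0 and 2 for brassinosteroid, 1 and 1 for auxin response factors, 1 and 2 for Aux/IAA, 2 and 6 for SAUR, 1 and 0 for GH3, gibberellin and ethylene, 1 and 2 for abscisic acid and 0 and 0 for cytokinin.

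Other wall lists had few called genes. Of 92 class III peroxidases, enzymes of wall cross-linking, 8 fell and 1 rose (median -0.20, camera adjusted p = 0.0667). The peroxidase list was called lower in 9 of 20 alternatives, among them slide 1 alone (median -0.71, 0.00884) and the fits without WT replicate 1 (-0.54, 0.00851), WT replicate 3 (-0.28, 0.0228) or smos1 replicate 3 (-0.49, 0.0219). With an estimated correlation the adjusted p in these 4 fits was 0.708, 0.663, 0.704 and 0.625. Os02g0833900 was 12.4-fold, Os05g0499300 10.9-fold and Os06g0274800 7.83-fold lower. For Os02g0833900 the fold ranged from 8.28 without WT replicate 1 to 18.5 without WT replicate 2. Of 53 lignin and phenylpropanoid genes 5 fell, all 5 of them laccases, including Os01g0842500 (8.08-fold) and Os11g0108700 (5.43-fold), and none rose. The fold of Os01g0842500 ranged from 6.08 without WT replicate 1 to 12.3 without WT replicate 3. The laccase Os12g0108000 was above background only in WT, at least 4.45-fold lower in smos1, but its log2 fold change was 0.75 under planned normexp correction. In the corrected normexp fit this laccase kept its lower direction. The list had a median of 0.05 and a mean of -0.16, with a camera adjusted p of 0.962 towards lower. None of 23 cellulose synthase superfamily genes was called, nor were the 3 genes each of secondary and primary wall cellulose synthesis (medians -0.46, -0.73 and -0.33, camera adjusted p of 0.231, 0.29 and 0.506). Within slide 1 the cellulose synthase superfamily and the lignin list were called lower (medians -0.76 and -0.40, camera adjusted p of 0.014 and 0.0382), with adjusted p of 0.708 and 0.744 with an estimated correlation. When adjusted over the list alone, 18 peroxidases and 9 lignin genes were lower, 1 and 3 were higher, and no cellulose synthase was in either group.

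Of 116 heat shock genes 4 fell, among them the small heat shock proteins Os10g0159700 (39.4-fold) and Os01g0136200 (3.03-fold), and none rose (median -0.05, camera adjusted p = 0.768). The fold of Os10g0159700 ranged from 27.2 without WT replicate 1 to 73.1 without WT replicate 2. Of 66 WRKY factors, regulators of defence, 1 rose (Os01g0584900, 3.88-fold) and 2 fell (Os02g0652100, 4.87-fold, and Os04g0471700, 11.4-fold, above background on 1 of 3 smos1 arrays), with a median of 0.37 (0.2), and the list was called higher without WT replicate 2 (0.0433). Os04g0471700 was 17.9-fold lower without WT replicate 2, and its log2 fold change was -0.39 under planned normexp correction (adjusted p = 0.796). In the list of 138 pathogenesis-related genes 4 rose and 10 fell (median 0.44, camera adjusted p = 0.137), and the list was called higher without WT replicate 2 (0.0494), without smos1 replicate 3 (0.0409) and without both (0.0167). With an estimated correlation the adjusted p was 0.426, 0.625 and 0.466 there, and 0.712 for WRKY factors without WT replicate 2. The members with the smallest p were no defence proteins but SMOS1 itself, an S-adenosylmethionine decarboxylase of polyamine synthesis (Os09g0424300, 13.8-fold lower) and a homocysteine methyltransferase of methionine synthesis (Os10g0422200, 20.2-fold lower). Of 11 phosphate starvation genes 2 purple acid phosphatases rose, Os12g0637000 (5.47-fold, above background on 1 of 3 WT arrays) and Os11g0151800 (3.40-fold). Os12g0637000 had a log2 fold change of 1.72 under planned normexp correction (adjusted p = 0.226). The median of the phosphate list was -0.08 and the mean 0.32 (camera adjusted p = 0.888 towards higher). None of 24 starch, 5 aquaporin and 3 wax genes was called (camera adjusted p of 0.886, 0.537 and 0.793). Their medians were 0, -0.10 and 0.80 and their means 0.14, 0.24 and -0.36, with camera leaning higher, lower and higher. Adjusted over the list alone, the genes higher and lower were 0 and 1 for heat shock, 2 and 3 for WRKY, 16 and 12 for pathogenesis-related, 2 and 0 for phosphate, 0 and 0 for starch, 0 and 2 for aquaporins and 1 and 1 for wax.

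Lists for other tissues and for the time of sampling were not called between the genotypes under the main settings, but they differed between arrays. None of 45 photosynthesis genes and none of 10 clock genes was called, over all genes or adjusted over the list alone (medians 0.61 and 0.66, camera adjusted p of 0.162 and 0.2). The photosynthesis list was called higher in smos1 in 7 of 20 alternatives and the clock list in 4. Within slide 1 their medians were 0.63 and 0.96 (camera adjusted p of 6.79e-05 and 0.00711), and without smos1 replicate 3 they were 2.00 and 1.16 (1.2e-05 and 0.0145). With an estimated correlation neither was called, with adjusted p of 0.722 and 0.708 within slide 1, 0.635 and 0.625 without smos1 replicate 3, and 0.847 and 0.745 over all arrays. At the preset correlation the photosynthesis list was also called without WT replicate 1 (0.0183) and without WT replicate 2 (0.0135), with adjusted p of 0.835 and 0.832 with an estimated correlation. Relative to the WT mean, the photosynthesis median was -2.42 in WT replicate 3 and -1.83 in smos1 replicate 3, against 0.86 and 1.51 in the other WT arrays and 2.09 and 1.91 in the other smos1 arrays. The clock medians were -0.98 and -0.65 in replicate 3 of WT and smos1, and between 0.17 and 1.28 on the other arrays. Leaving out smos1 replicate 3 alone therefore keeps the low WT replicate 3 in the comparison. Leaving out WT replicate 1 or 2 gives WT replicate 3 more weight. The calls in those fits cannot be told apart from the shift of replicate 3. None of 5 KNOX genes was called, in a list fixed for the shoot meristem that also took in the class 2 member Os06g0646600 (median 0.77, camera adjusted p = 0.405). Of 13 MADS-box genes Os03g0753100 was at least 4.82-fold higher and Os01g0726400, above background on 1 of 3 smos1 arrays, was 13.1-fold lower in smos1 (median 0.24, camera adjusted p = 0.351). Under planned normexp correction their log2 fold changes were 1.61 and -0.27, with adjusted p of 0.277 and 0.857. Of 2 root markers the silicon channel gene LSI1 (Os02g0745100) was 5.89-fold higher, and RCc3 (Os02g0662000) had a log2 fold change of -2.19 with an adjusted p of 0.172, for a median of 0.18. Adjusted over the list alone, 1 KNOX gene, 1 MADS-box gene and 1 root marker were lower, and 2 MADS-box genes and 1 root marker were higher.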

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

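The test in this part was chosen after the values had been seen. Probes for microRNA genes carry no rice locus and enter no count of genes. Of 138 tested, 3 were called, against 1595 of all 36024 tested probes, so microRNA probes were not called more often than others. All 3 were higher in smos1 than in the WT controls and not well above background on any WT array. Their values are from the main fit, and no fit without single arrays, within slide 1 or under normexp correction is given for them. These were probes of osa-miR530 (log2 fold change 2.30 ± 0.37, adjusted p = 0.0298, at least 3.52-fold higher), osa-miR169g (2.99 ± 0.58, adjusted p = 0.043, at least 5.37-fold) and osa-miR169a (2.72 ± 0.53, adjusted p = 0.0444, at least 2.83-fold), by limma on 3 arrays per genotype. The labelling reads polyadenylated RNA, and no separate measurement of mature microRNA was analysed here.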

How the results depend on the processing

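The fit without 2 arrays, the corrected normexp fit and the estimated correlation under each alternative were chosen after the data had been seen. SMOS1 stayed lower in every setting tried. It lost its call under planned normexp correction, at a log2 fold change of -3.83 (adjusted p = 0.0973, range over all alternatives 0.0131 to 0.0973). Leaving out 1 array gave a log2 fold change between -5.19 and -4.23, and the call was lost without WT replicate 1 or 3 or smos1 replicate 1 or 2. Planned normexp called 6 genes, 6 higher and 0 lower, and turned the laccase Os12g0108000 to 0.75. On smos1 replicate 3, 10 spots had a local background over 10 times the array median, the highest at 27400. With those set to the median, normexp called 908 genes, 216 higher and 692 lower, and the 1259 genes, this laccase among them, kept their sign. Requiring all 6 arrays above background left 182 higher, from fewer genes tested. The slide as a fixed block and slide 1 alone both gave 186 calls, 89 higher and 97 lower, from 4 arrays with both genotypes on a slide. The slide as a random block (correlation 0.31) gave 2274, 722 higher and 1552 lower, and the cause was not tested. Leaving out 1 array gave 12 to 3356 calls, 11 to 1103 higher and 0 to 2253 lower. Without both WT replicate 2 and smos1 replicate 3 there were 4953, with 1948 higher and 3005 lower, and SMOS1 was at -5.41. Quantile normalization, median centring, the authors' table, no filter on dim probes, the variance trend and the mean over probes kept the counts within 1.5 times, and all 1259 genes kept their sign under each of these. These settings use the same arrays that chose the genes, so the kept signs are no independent check.

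The replicate number as a block gave 1831 calls, 635 of them higher. The same-numbered arrays' deviations from their group means correlated across genes at 0.35, 0.04 and 0.52 for replicates 1, 2 and 3. WT replicates 1 and 3 correlated best with the same-numbered smos1 array, but WT replicate 2 with smos1 replicate 1 (0.33). A pairing was therefore neither shown nor excluded, and the main fit left the samples unpaired. A shift shared by both replicate 3 arrays thus adds to the residual spread of the main fit. With the block the photosynthesis list was called higher (median 0.61, camera adjusted p = 0.00101, and 0.778 with an estimated correlation). Of the 11 lists called by camera, 0 were called with an estimated correlation and 4 by fry. Over 20 settings 7 lists kept their call throughout, the xyloglucan and pectin lists lost it in 1 each, the EXORDIUM list in 2 and the jasmonate list in 4. Of the lists not called, the peroxidase list gained a call in 9 settings, the brassinosteroid and photosynthesis lists in 7 each, the clock list in 4, the GH3 and pathogenesis-related lists in 3 each, the cellulose synthase and lignin lists in 2 each and the abscisic acid and WRKY lists in 1 each. Of these 39 gained calls, 38 could be tested with an estimated correlation and 0 were called (lowest adjusted p = 0.426). That test has few degrees of freedom here, so this does not show that correlation between genes made the calls. In these counts of settings, the slide as a fixed block and slide 1 alone rest on the same 4 arrays. Calls gained or lost in both therefore come from the same comparison, and the cellulose synthase and lignin lists gained theirs in these settings alone. Signals near background limited 61 called genes in WT and 62 in smos1 to bounds.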

Other observations

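All tests in this part were chosen after the data had been seen, apart from those of shared probe sequence and of genes matched in signal, which were set before their results were known. Among lists added then, 51 cyclins and cyclin-dependent kinases, the engine of the cell cycle, had 12 members lower and 0 higher in smos1 (median log2 fold change -1.25, camera adjusted p = 6.51e-07, adjusted p = 0.407 with an estimated correlation). Of 20 small heat shock proteins 3 fell and 0 rose (median -0.87, camera adjusted p = 0.0591, adjusted p = 0.382 with an estimated correlation). The self-contained test fry, which asks whether a list's genes move one way on balance, called this list lower (adjusted p = 0.0176) and the cyclin list too (0.0218), and no other added list. Of 65 ERF-domain factors 3 rose and 4 fell, and of 52 NAC factors, found by the NAM domain, 2 rose and 1 fell (camera adjusted p of 0.344 for both). None of 21 terpene synthases was called (median 0.70, camera adjusted p = 0.109). In the cleaned list of 70 pathogenesis-related proteins 3 rose and 6 fell (median 0.47, camera adjusted p = 0.165).

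Genes above background on all WT arrays and on no smos1 array, chosen after their values were seen, included a regulator of development and replication factors. A leafy-like factor (Os04g0598300) was at least 15.1-fold lower in smos1 (limma adjusted p = 0.0305). A DNA polymerase epsilon subunit (Os05g0160800) and a CDC45-like protein (Os12g0124700), which act in DNA replication, were at least 13.9- and 9.02-fold lower (0.0386 and 0.0333). In the other direction, Os03g0115800, a conserved hypothetical protein, averaged -10.29 in WT and 3.68 in smos1, at least 7040-fold higher (limma adjusted p = 7.14e-05). Os06g0265100, a hypothetical protein, was at least 578-fold higher.

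The real grouping of the 6 arrays called 1259 genes and each of the other 9 groupings into 3 and 3 called 0. Thus 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05.

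On chromosome 11, 7 loci above background only in smos1 lay within 50 consecutive tested loci, from Os11g0214400 to Os11g0226800. Random placement of the 24 called genes above background only in smos1 and at least 8-fold higher reached at most 4 in 10000 draws (median 2, permutation p = 1e-04, the smallest these draws can give), which argues against chance placement, while the 45 such genes above background only in WT and at least 8-fold lower reached 3 (permutation p = 0.14). With no smallest fold, the 61 genes above background only in smos1 again reached 7 (highest random 6, permutation p = 1e-04) and the 62 above background only in WT reached 3 (permutation p = 0.32). Probes of near-identical sequence reading the same RNA are argued against as well. Of the 7 loci, 0 had a probe sharing 20 or more bases with that of another, and the longest shared run was 8 of 60 bases. Probes on different parts of a transcript need share no bases, so a transcript that spans several of these loci was not tested. A candidate explanation is a DNA difference between the lines at this segment, where 9 of 37 tested loci were called, all of them higher, and 28 were not. An effect of the mutated gene on these loci stays open too, and the explanations cannot be told apart for these loci because each genotype is 1 line and no DNA was measured.

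Lists of genes of dividing cells were called lower in smos1 at camera's preset correlation, and WT replicate 2 lay between the groups. For tubulins it lay close to the other WT arrays. Mixing of smos1 RNA into WT replicate 2 is argued against, because 16 probes of 15 genes, above background on all smos1 arrays, on neither other WT array and at least 64-fold brighter in smos1 than there, had a median log2 difference of -7.14 between WT replicate 2 and smos1 (quartiles -9.03 and -6.18), while the histone medians would need a share of 89.4%. The histone list had a median of -1.36 to -1.60 under 5 other scalings, which argues against the choice among these scalings as the whole cause. Under each of them the median log2 fold change over all genes lay between -0.064 and 0.363. A scaling error that all of them share was therefore not tested. Across 24485 genes outside the growth lists, which are not independent, WT replicate 2 differed from another WT array as smos1 differed from the remaining one. The correlations were 0.36 and 0.65, so this array lay between the groups beyond the growth lists, as the first principal component had already shown. Any cause that places it there would give such correlations. A growth state of the sampled sheaths that also varies within WT is therefore not singled out. It stays open, as does a genotype effect on growth.

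Photosynthesis genes were low in replicate 3 of both genotypes, with medians of -3.64 in WT and -3.68 in smos1 against replicates 1 and 2 of the same genotype, and 44 of 45 genes were lower in both. A slide effect that follows signal level is argued against, since 511 genes matched in signal had medians of -0.06 and 0.10. Another hour of sampling may have contributed. The 10 clock genes, averaged over the genotypes, had a mean absolute change of 2 log2 units against 0.56 for random genes matched in signal (permutation p = 1e-04, the smallest that the draws can give), with 7 lower and 1 higher in both genotypes. LHY (-1.27 in WT and 0.85 in smos1) and ELF3 (0.83 and -0.32) moved in opposite directions, which the average over genotypes does not show. Both replicate 3 arrays lay alone on their slides, so a slide effect of another kind and a difference in the sampled tissue stay untested.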
